A study of Arabidopsis thaliana with 9 samples.

How the data were processed

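Total RNA from inflorescence tips of Arabidopsis thaliana was measured on 9 Affymetrix expression arrays with 1 colour, 3 for the wild type (WT, accession Col-0), 3 for the receptor mutant er-2 and 3 for the ligand double mutant epfl4 epfl6. Per the labels, the plants were 33 days past germination, grew on soil under continuous light, and received no treatment, and each sample was a biological replicate. Biotin-labelled cRNA was made from total RNA with a kit that primes at the poly(A) tail, per the labels' protocols. No label says how many plants were pooled for a sample or how the buds were staged. Except for those from random draws of probe sets and from the set test camera, the p-values below measure the spread between these samples. The random draws take probe sets, not samples, as units. The set test compares the genes of a list with the other genes and, at its preset correlation, takes genes as nearly independent units.

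The deposited table holds log2 expression values, 1 per probe set and array. Per the submitters' processing notes, RMA and limma were used, with no version or design given in the sources used here. The values ran from 1.74 to 13.47 with array medians between 5.81 and 5.91, the form that RMA gives after background correction, quantile normalization and summarization. They were used as deposited, with no further normalization. Of 22810 probe sets, 64 Affymetrix control probe sets were kept out of the tests, which left 22746. The number of arrays limits the precision, and arrays give no read depth.

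Gene names came from the platform's annotation, with symbols updated through Entrez identifiers in a RefSeq gene table whose genome build was not matched to the array. That table served only for names and for the order of genes along chromosomes. Of the tested probe sets, 13513 had 1 gene, 503 had several and 8730 were not listed, and no gene was named from the last 2 kinds. Among those with 1 gene, 1580 carried a descriptive symbol and 11933 had a locus tag as their symbol. ER, EPFL4 and EPFL6 had no named probe set, so transcripts of the mutated genes were not analysed here.

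The main test was limma 3.58.1 in R 4.3.3 with a mean per genotype over all 9 arrays and moderated variances. The 4 contrasts were er-2 against WT, epfl4 epfl6 against WT, er-2 against epfl4 epfl6, and the mean of both mutants against WT. All tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05 with no fold minimum. Standard errors are those of the limma fit, with 3 arrays per genotype. On simulated data with the real means and spreads, the fit on 22746 probe sets recovered 71.6% of log2 changes of 0.5 and 100% of those of 1 for er-2 against WT, with 6 false calls. For epfl4 epfl6 against WT it recovered 74.6% of log2 changes of 0.5, with 10 false calls.

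Before the data were examined, 26 gene lists with 372 members were fixed for the tissues, hormones and stresses of an inflorescence. Of these members, 50 had a named probe set. A set test, limma's camera with a preset correlation of 0.01, was run on the 7 lists with at least 3 named members, using for each gene the probe set with the highest mean, and adjusted over the lists of a comparison. An estimated correlation and limma's fry served as alternatives. After the annotation had been seen, but before any comparison was computed, 28 families of at least 8 genes with a shared symbol stem, the chloroplast genome and the mitochondrial genome among them, were added and tested the same way.

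Genes were named by a rule fixed in advance. In each comparison it took, among probe sets with 1 gene that were called and whose 3 arrays of one genotype all lay above or below the 3 of the other, the 10 largest rises and the 10 largest falls. It further took 10 changed the same way in both mutants, and up to 4 members of each list by smallest p. Because most symbols were locus tags, the same rule was applied again to descriptive symbols only, a choice made after the annotation had been seen.

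Both mutants were compared with the same WT arrays. Unchanged groups sharing these arrays were therefore simulated 100 times to give the correlation and overlap that arise without any effect. Alternatives fixed in advance were quantile normalization again, median centring, leaving out the 30% dimmest probe sets, a variance trend with robust estimation, array weights, the replicate number as a block, a 2-fold minimum, fits on 6 arrays, and leaving out each array in turn. A fit with an RNA quality index as a covariate was added after seeing the data. For single named genes, 11 alternatives were run. These were quantile normalization again, median centring, the variance trend, array weights, the replicate block, and each of the 6 arrays compared left out. The covariate fit was not among them. For single values over the 9 arrays, exact permutation tests over all 280 ways of forming 3 groups of 3 arrays were used.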

Results

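Inflorescence tips of wild-type plants and of 2 mutant genotypes were profiled at 33 days after germination, with 3 arrays per genotype and 9 arrays in all; the number of arrays limits the precision. ERECTA (ER) is a receptor-like kinase that promotes stem and pedicel elongation, and er-2 is a mutant allele of it. EPFL4 and EPFL6 encode secreted peptides of the epidermal patterning factor family that act as ligands of ER, and the double mutant carries mutations in both genes. The study asked how loss of the receptor and loss of the ligands change gene expression in a tissue where the ligands come from the endodermis and the receptor acts in the phloem. Arrays of the same genotype correlated at r = 0.9945 to 0.9973 across probe sets, and arrays of different genotypes at 0.9816 to 0.9907. Transcripts of ER, EPFL4 and EPFL6 themselves were not analysed here, so the expression values gave no check of the genotype labels.

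The control probe sets for RNA and labelling quality differed between the genotypes. The signal at the 3′ end of actin, GAPDH and ubiquitin transcripts exceeded that at the 5′ end by a mean log2 difference of 2.45 ± 0.138 (SD, n = 3) in WT. This difference was 2.13 ± 0.081 (SD, n = 3) in er-2 and 1.67 ± 0.0507 (SD, n = 3) in epfl4 epfl6. The genotypes did not overlap, and the real grouping separated the arrays more than any other of the 280 groupings (exact permutation test, p = 0.00357, the smallest it can give). The 25S ribosomal RNA control was at 11.84 ± 0.0274 (SD, n = 3) in WT, at 11.84 ± 0.105 in er-2 and at 11.30 ± 0.150 in epfl4 epfl6 (exact permutation test, p = 0.0357). The 3′ minus 5′ difference runs along with every genotype comparison given here, and the lower 25S rRNA control with those that involve epfl4 epfl6.

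**Figure D1:**
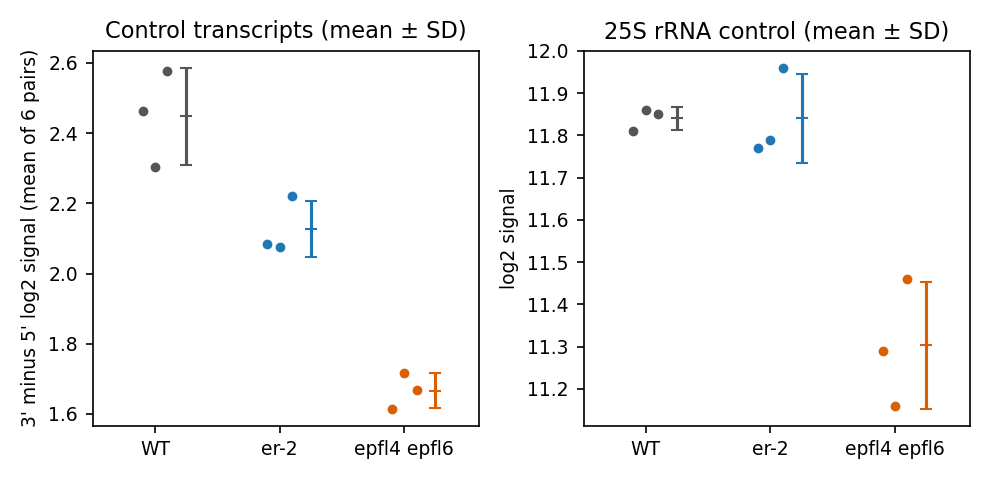
Control probe sets on the 9 arrays by genotype. Left, log2 signal at the 3′ end minus the 5′ end, averaged over 6 control pairs; right, log2 signal of the 25S rRNA control; points are arrays and bars are the mean ± SD of 3 arrays. The 3′ minus 5′ difference falls from 2.45 in WT to 1.67 in epfl4 epfl6, with no overlap between genotypes.

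The comparison of er-2 with WT asked what changes when the receptor is lost. The expansin-like gene EXLB1 (AT4G17030) had the largest rise among probe sets assigned to 1 gene. It rose by 2.58 ± 0.101 on the log2 scale (SE; limma adjusted p = 4.01e-07), and the expansin gene EXPA9 (AT5G02260) rose by 1.33 ± 0.114 (adjusted p = 6.35e-05). SWEET11 (AT3G48740), a sucrose exporter of the phloem, rose by 1.75 ± 0.139 (adjusted p = 3.94e-05). GH3.9 (AT2G47750), of the family of auxin-conjugating enzymes, rose by 1.70 ± 0.131 (adjusted p = 3.24e-05), and the β-glucosidase family gene BGLU33 (AT2G32860) rose by 1.58 ± 0.109 (adjusted p = 1.5e-05). CHX20 (AT3G53720), a cation exchanger of guard cells, rose by 1.13, the carboxypeptidase-like gene scpl31 by 1.38 and the glutathione transferase gene GSTF4 by 1.07. Rises of 1.83 to 2.31 were found for 9 genes known here only by locus tag, AT3G28270, with 2.31, being the largest of these.

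The largest falls in er-2 were larger than its largest rises. ECS1 (AT1G31580) fell from a log2 signal of 10.88 ± 0.109 in WT to 4.38 ± 0.157 (SD, n = 3), a change of −6.50 ± 0.100 (SE; limma adjusted p = 3.69e-10). AT1G23960 changed by −5.34, to a signal below the lower quartile of every array, AT1G11280 by −4.49 and AT1G06640 by −3.18. BGLU28 (AT2G44460), another β-glucosidase family gene, fell by 3.04 ± 0.0555 (SE; adjusted p = 9.91e-10). CLE44 (AT4G13195), which encodes a peptide of the phloem that acts on the procambium, fell by 1.12 ± 0.116 (adjusted p = 0.000188). Further log2 changes were −1.53 for QQS (AT3G30720), a gene with a known effect on starch content, −1.24 for the jasmonate methyltransferase gene JMT and −1.22 for the expansin-like gene EXLA1. They were −1.18 for the subtilase gene SBT5.4 and −1.15 for the asparaginase gene ASPGB1. The call of OCT1, an organic cation transporter gene with a change of −1.13, was lost on leaving out WT replicate 2 (adjusted p = 0.0502, and from 0.0027 over the other alternatives).

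Many of these genes lay on the upper part of chromosome 1. A change was taken as er-2-specific where it was called against WT and against epfl4 epfl6 in the same direction, and where the change in epfl4 epfl6 was less than 50% as large. Of 51 such changes of at least 2-fold among 13367 named probe sets of the 5 nuclear chromosomes, 38 were on chromosome 1. The upper part of that chromosome, from its top to AT1G33700, held 32 of them in 1574 measured probe sets, or 62.7% of the changes in 11.8% of the probe sets. Its end was set at the largest gap between these same changes, 717 probe sets before AT1G55450, so this share describes the pattern and is no test of it. Among these 32 were ECS1, AT1G23960, AT1G11280, AT1G06640 and JMT, which were lower in er-2, and the metallothionein gene MT1C (AT1G07610), which was higher by 1.31 ± 0.116 (SE; limma adjusted p = 7.44e-05). The direction was mixed, with 13 higher and 19 lower.

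**Figure D2:**
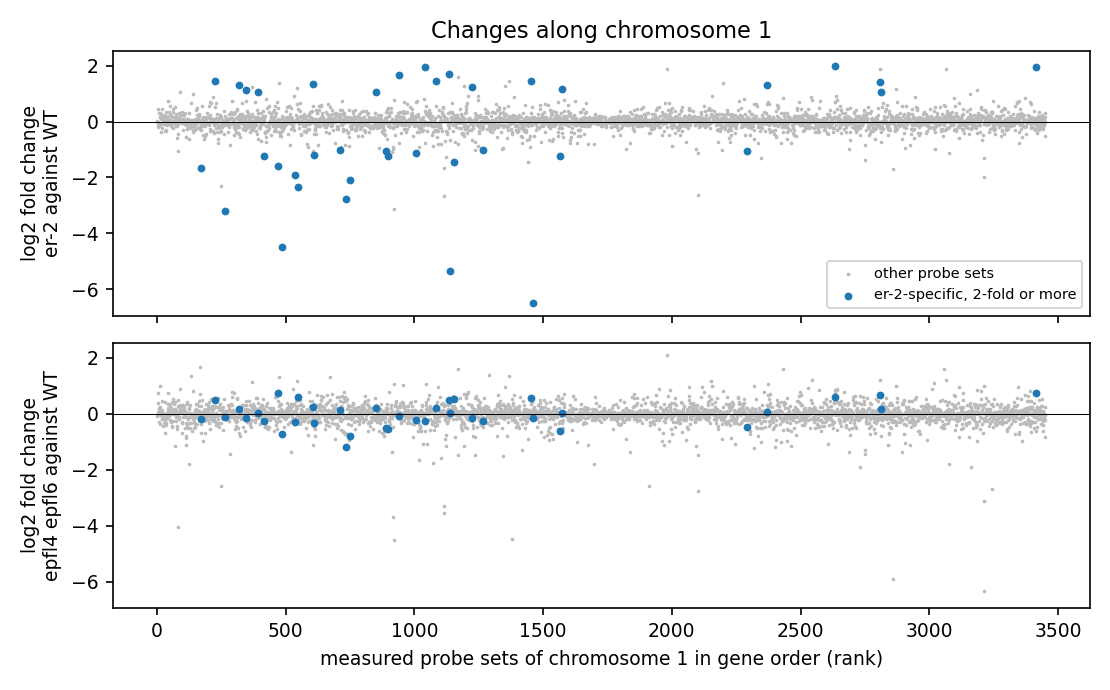
Log2 fold changes of er-2 (top) and epfl4 epfl6 (bottom) against WT for the 3451 measured probe sets of chromosome 1, in gene order. Blue points are the 38 er-2-specific changes of at least 2-fold; 32 of them lie among the first 1574 probe sets.

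In all, 4722 of 22746 probe sets were called in er-2 against WT by limma, 2673 higher and 2049 lower. For every gene given here as having risen, fallen or differed, the 3 arrays of each genotype compared lay fully apart, which chance gives in 10% of genes. The median size of a called log2 change was 0.404, and 328 called changes were at least 2-fold, 162 up and 166 down. The 3′ minus 5′ difference of the control transcripts was 0.321 lower in er-2 than in WT, and with it as a covariate 648 probe sets were called.

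The comparison of epfl4 epfl6 with WT asked what changes when the ligands are lost. The largest changes were falls, and 2 of the genes concerned are known from anthers. ATA27 (AT1G75940), an anther gene, fell from 8.95 ± 0.696 in WT to 2.61 ± 0.224 (SD, n = 3), a change of −6.34 ± 0.733 (SE; limma adjusted p = 0.000175). SHT (AT2G19070), which encodes an acyltransferase of the tapetum that makes pollen coat phenolamides, fell by 4.66 ± 0.538 (adjusted p = 0.000174). AT1G68875 changed by −5.91 ± 0.612 and AT5G13380 by −5.20 ± 0.575. The epfl4 epfl6 means of ATA27 and AT1G68875 lay below the lower quartile of every array (3.21 to 3.33), where signal over background was not tested, so these 2 sizes are fitted values and the true sizes were not determined. In er-2 against WT the log2 changes were −1.98 for ATA27 (adjusted p = 0.0877), −1.90 for SHT (adjusted p = 0.0326), −1.84 for AT5G13380 (adjusted p = 0.0477) and −1.70 for AT1G68875 (adjusted p = 0.08), with er-2 arrays that overlapped those of WT for each. QQS fell by 4.44 ± 0.139 (adjusted p = 5.18e-07), a larger fall than in er-2. BGLU28 fell by 1.43 ± 0.0555 (adjusted p = 7.57e-07). Further log2 changes were −2.02 for SBT5.4, −1.80 for OCT1, −1.49 for TBL38 of a cell wall acetylation family and −1.30 for the aspartyl protease gene UND. The mitochondrial gene nad4, for a subunit of respiratory complex I, fell by 1.52 ± 0.0944 (adjusted p = 1.03e-05), next to the lower 25S rRNA control in this mutant.

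The rises in epfl4 epfl6 were smaller. The jacalin-related lectin gene JAL23 (AT2G39330) rose by 1.75 ± 0.169 (SE; limma adjusted p = 7.34e-05), and EXLB1 rose by 1.61 ± 0.101 (adjusted p = 1.05e-05). EXPA9 rose by 1.42, scpl31 by 1.30, GH3.9 by 1.28 and CHX20 by 1.15. The glucosinolate transporter gene GTR2 rose by 1.17, and 2 genes of xyloglucan-modifying enzymes, XTH32 and XTH19, rose by 1.08 and 1.07, XTH19 from a WT signal below the lower quartile of every array. AT1G49310 had the largest rise among probe sets assigned to 1 gene, 2.1 ± 0.173 (adjusted p = 3.44e-05). In all, 7707 probe sets were called, 4079 higher and 3628 lower (4951 and 2922 after median centring), and 512 called changes were at least 2-fold, of which 354 were falls. The median size of a called change was 0.411. The 3′ minus 5′ difference was 0.782 lower in epfl4 epfl6 than in WT. With it as a covariate 1 probe set was called, since the index and the genotype were nearly inseparable and standard errors grew 4.15 times.

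**Figure D3:**
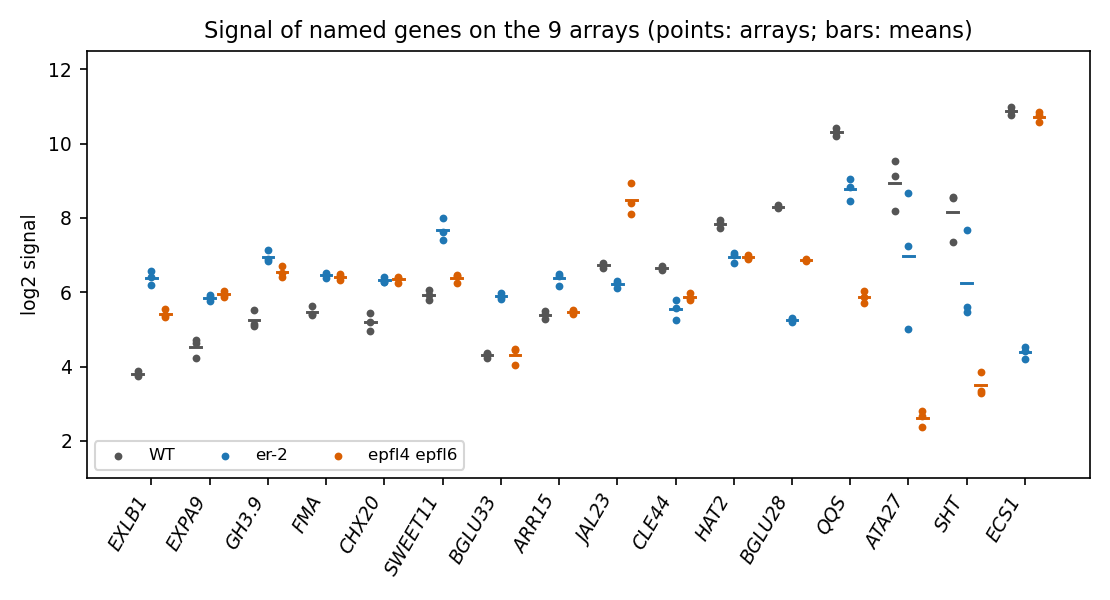
Log2 signal of 16 named genes on the 9 arrays, by genotype; points are arrays and bars are means of 3 arrays. ECS1 is low on the er-2 arrays only, ATA27 and SHT are low on the epfl4 epfl6 arrays and spread widely on the er-2 arrays, and EXLB1, EXPA9, GH3.9, FAMA (shown as FMA) and CHX20 are above WT in both mutants.

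The list of stomatal lineage genes held FAMA (listed as FMA, AT3G24140), MUTE (AT3G06120) and SPCH, 3 transcription factor genes that act in turn on the way to guard cells. FAMA, the last to act, rose by 0.98 ± 0.0806 (SE; limma adjusted p = 4.76e-05) in er-2 and by 0.95 (adjusted p = 4.06e-05) in epfl4 epfl6. MUTE rose by 0.53 in epfl4 epfl6 (adjusted p = 0.00133) and had a log2 change of 0.08 in er-2 (adjusted p = 0.606), and the difference between the mutants passed the test (adjusted p = 0.00648). SPCH was not called in either mutant. In er-2, 1 of the 3 measured stomatal members was called over all probe sets and 2 when adjusted over the list alone; in epfl4 epfl6 it was 2 and 2. The list was higher in er-2 with a camera adjusted p of 0.0398 (adjusted p = 0.261 with an estimated correlation). That call was lost without WT replicate 2 (0.114), without er-2 replicate 3 (0.121) and without the dimmest probe sets (0.0905), within a range of 0.0174 to 0.121 over the alternatives. In epfl4 epfl6 the camera adjusted p was 0.067, within a range of 0.0484 (without WT replicate 3) to 0.135 over the alternatives.

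The 3 measured photosynthesis genes were called higher in both mutants. All 3, the antenna protein gene LHCB4.1, the photosystem I gene PSAN and the Rubisco activase gene RCA (AT2G39730), were called higher in er-2, with log2 changes from 0.30 to 0.49, also when adjusted over the list alone. RCA rose by 0.49 ± 0.0759 (SE; limma adjusted p = 0.00159) in er-2 and by 0.48 (adjusted p = 0.000975) in epfl4 epfl6. All 3 were called higher in epfl4 epfl6 too, over all probe sets and adjusted over the list alone, but the call of LHCB4.1, with a rise of 0.18, was lost on leaving out any 1 of the 6 arrays, with quantile normalization again and with the replicate number as a block (adjusted p from 0.00871 to 0.238 over all alternatives). The list was higher in er-2 with a camera adjusted p of 0.0128 (adjusted p = 0.151 with an estimated correlation). In epfl4 epfl6 it was 0.0533, and it passed without WT replicate 1 (0.0387), WT replicate 3 (0.0484) or epfl4 epfl6 replicate 2 (0.0441), over a range up to 0.135.

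Of 4 measured anther and tapetum genes, 2 fell in er-2 and 3 in epfl4 epfl6. The tapetum regulator gene AMS (AT2G16910) fell by 0.36 ± 0.0764 (SE; limma adjusted p = 0.00928) in er-2 and changed by −0.40 (adjusted p = 0.0028) in epfl4 epfl6. A9 (AT5G07230) fell by 0.83 in epfl4 epfl6 (adjusted p = 0.00107) and had a log2 change of −0.36 in er-2 (adjusted p = 0.091). EMS1, a receptor kinase gene needed for tapetum fate, changed by −0.37 in er-2 and by −0.32 in epfl4 epfl6. Its calls were lost in er-2 without WT replicate 2, WT replicate 3 or er-2 replicate 2 (adjusted p from 0.00356 to 0.0563 over all alternatives). They were lost in epfl4 epfl6 without WT replicate 2, WT replicate 3, or epfl4 epfl6 replicate 1 or 3 (0.00596 to 0.0683). The sporogenesis gene SPL was not called. In er-2, 2 of 4 members were called lower, and 3 adjusted over the list alone; in epfl4 epfl6 it was 3 and 3. The list was lower in er-2 with a camera adjusted p of 0.0128 (adjusted p = 0.261 with an estimated correlation), which was 0.053 without WT replicate 2 and otherwise 0.00916 or above. In epfl4 epfl6 it was 0.0501, within a range of 0.0249 to 0.114 over the alternatives, 7 of which brought it under the threshold. The 3′ minus 5′ difference of the control transcripts fell along with these genes, from 2.45 in WT to 2.13 in er-2 and 1.67 in epfl4 epfl6.

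Auxin response genes changed in both directions. HAT2 (AT5G47370), an auxin-induced homeobox gene, fell by 0.88 ± 0.0851 (SE; limma adjusted p = 0.000127) in er-2 and changed by −0.90 (adjusted p = 6.53e-05) in epfl4 epfl6. GH3.3 (AT2G23170) fell by 1.24 ± 0.186 in epfl4 epfl6 (adjusted p = 0.000724). Its change in er-2 was −0.69, a call lost with a variance trend and robust estimation and on leaving out WT replicate 1 or 2 or er-2 replicate 1 or 3 (adjusted p from 0.00867 to 0.0991 over all alternatives). WES1 (AT4G27260), another auxin-conjugating enzyme gene, rose by 0.74 in er-2 (adjusted p = 0.000274), had a log2 change of 0.15 in epfl4 epfl6 (adjusted p = 0.208), and differed between the mutants (adjusted p = 0.0013). IAA29 and LBD29 were not called, LBD29 at a signal below the lower quartile of every array in all genotypes. Over all probe sets 3 of 5 members were called in er-2, and 3 adjusted over the list alone; in epfl4 epfl6 it was 2 and 2. The camera adjusted p was 0.479 in er-2 and 0.133 in epfl4 epfl6.

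Of 6 measured cell wall loosening genes, 2 rose and 1 fell in er-2, and 3 rose in epfl4 epfl6, with the same counts adjusted over the list alone. EXPA16 (AT3G55500) rose by 0.59 ± 0.0907 (SE; limma adjusted p = 0.00168) in er-2 and by 0.73 (adjusted p = 0.000269) in epfl4 epfl6, and EXPA15 rose by 0.32 in epfl4 epfl6 (adjusted p = 0.00651). XTH16 fell by 0.47 in er-2 (adjusted p = 0.00278). The count in er-2 includes EXPA8, with a log2 change of 0.55, whose call was lost without WT replicate 3 or er-2 replicate 1 or 2 (adjusted p from 0.000786 to 0.06 over all alternatives). The count in epfl4 epfl6 includes EXPA4, with a change of 0.29, whose call was lost in 6 of 11 alternatives (0.0138 to 0.139): quantile normalization again, the replicate number as a block, and WT replicate 1 or 2 or epfl4 epfl6 replicate 1 or 3 left out. The camera adjusted p was 0.567 in er-2 and 0.116 in epfl4 epfl6. Of 4 procambium and cambium genes only CLE44 was called, lower in er-2 and in epfl4 epfl6, also when adjusted over the list alone. The camera adjusted p was 0.886 in er-2, where the median of the list was positive and its mean negative, and 0.496 in epfl4 epfl6. Of the 3 gibberellin receptor genes, GID1A (AT3G05120) rose by 0.62 ± 0.083 in er-2 (adjusted p = 0.000761) and by 0.37 in epfl4 epfl6 (adjusted p = 0.00703). Adjusted over the list alone, 1 member, GID1A, was called in er-2. In epfl4 epfl6 it was 2, GID1A higher and GID1C lower (log2 change −0.30, adjusted p = 0.0317 over the list alone). The median of the list there was −0.02 and the mean 0.01. The camera adjusted p was 0.486 in er-2 and 0.875 in epfl4 epfl6.

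Of the other 19 lists, 15 had 1 or 2 named members and 4, those of xylem and secondary wall, floral organ identity, brassinosteroid, and salicylate and defence, had none. The type-A cytokinin response regulator gene ARR15 (AT1G74890) rose by 0.98 ± 0.094 (SE; limma adjusted p = 0.00012) in er-2, with a log2 change of 0.09 in epfl4 epfl6, whereas RR16 (ARR16) fell by 0.92 ± 0.173 in epfl4 epfl6 (adjusted p = 0.00253), with a log2 change of −0.30 in er-2. The difference between the mutants passed the test for ARR15 (adjusted p = 0.000325) and for RR16 (adjusted p = 0.031). PRL, a DNA replication licensing gene, fell by 0.59 in er-2 (adjusted p = 0.000773) and changed by −0.42 in epfl4 epfl6 (adjusted p = 0.00267). Of the mitosis list, the Aurora kinase gene AUR2 rose by 0.26 in epfl4 epfl6 (adjusted p = 0.0104) and had a log2 change of −0.20 in er-2 (adjusted p = 0.0455), a call lost in 7 of 11 alternatives (0.0179 to 0.145), among them any WT replicate or er-2 replicate 1 or 2 left out, and the mutants differed (adjusted p = 0.00122). AUR1 had a change of −0.27 in er-2 (adjusted p = 0.0419), a call lost in 6 of 11 alternatives (0.0141 to 0.128), among them WT replicate 1 or 3 or any er-2 replicate left out, and of −0.08 in epfl4 epfl6 (adjusted p = 0.502). The cold-response gene COR15A had a change of −0.89 in epfl4 epfl6 (adjusted p = 0.0171), a call lost with a variance trend and robust estimation and without epfl4 epfl6 replicate 2 (0.00838 to 0.0618 over all alternatives), and of −0.52 in er-2 (adjusted p = 0.167). STZ (ZAT10), the other measured gene of that list, was not called. Its log2 change was 1.38 in epfl4 epfl6 (adjusted p = 0.0538, 0.0028 to 0.176 over all alternatives) and −0.03 in er-2 (adjusted p = 0.971). The clock gene GI fell by 0.56 in epfl4 epfl6 (adjusted p = 0.00111) and had a log2 change of 0.14 in er-2. The endodermis gene SCL23 (AT5G41920) rose by 0.39 in er-2 (adjusted p = 0.00311) and by 0.26 in epfl4 epfl6 (adjusted p = 0.0132). The other measured gene of the endodermis list, JKD, went the other way, with a log2 change of −0.33 in er-2 (adjusted p = 0.085) and of −0.37 in epfl4 epfl6 (adjusted p = 0.0397), a call lost in 7 of 11 alternatives (0.00705 to 0.133), among them WT replicate 1 or 3 or any epfl4 epfl6 replicate left out. The leaf polarity gene PHV fell by 0.47 (adjusted p = 0.00142) and the epidermal receptor kinase gene CR4 (ACR4) changed by −0.37 (adjusted p = 0.00747) in epfl4 epfl6. In er-2 the change of CR4 was −0.17 (adjusted p = 0.193) and that of PHV was −0.31 (adjusted p = 0.0235), a call lost without WT replicate 2 or 3 or er-2 replicate 1 or 2 (0.00556 to 0.0858 over all alternatives).

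Within the ERECTA pathway list, STOMAGEN, a peptide gene of the same family as the ligands, had a log2 change of 0.20 in er-2 (adjusted p = 0.0398), a call lost in 6 of 11 alternatives (adjusted p from 0.0172 to 0.138), among them without WT replicate 1 or 3 or er-2 replicate 1 or 2. The other measured member, EPFL1 (AT5G10310), was not called in either mutant. CLV3 and UFO of the shoot meristem, MGH3 of mature pollen, PDF1.2 of the jasmonate response, ATHSP22.0 of the heat shock response and DFR of flavonoid synthesis were not called in either mutant. Of these, CLV3, ATHSP22.0 and DFR had means below the lower quartile of every array in all genotypes, and the means of MGH3 lay within the range of the lower quartiles. The phloem gene OPS had a log2 change of 0.48 in epfl4 epfl6 (adjusted p = 0.0131), which had adjusted p = 0.0503 without WT replicate 2 and from 0.00446 over the other alternatives.

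The comparison of the mutants' changes asked how far loss of the receptor and loss of the ligands act on the same genes. Across the 22746 probe sets the log2 fold changes of er-2 and epfl4 epfl6 correlated at r = 0.657, where simulated unchanged groups sharing the WT arrays gave 0.50 on average and at most 0.532. The covariance was 0.0827 against 0.00537 in the simulations, a difference of 0.0773. In total 3210 probe sets were called in the same direction in both mutants, 1785 higher and 1425 lower. Independent lists of these lengths would share 806, and the simulated unchanged groups shared at most 1. The simulations drew each probe set independently, so they lack the co-variation of real arrays and may understate what sharing WT gives. The WT arrays were too few to give each mutant its own WT replicates, so part of the excess may come from sharing them. The 3′ minus 5′ difference was lower than in WT in both mutants, and the shared changes were not counted with it as a covariate. A further 130 probe sets were called in opposite directions. Of the 60 among them named on the 5 nuclear chromosomes, 27 lay on the upper part of chromosome 1, which held 11.8% of such named probe sets. Some of these, such as AT1G12400, were among the changes that had set the end of that part, so this share is no test. The mean of both mutants differed from WT at 7005 probe sets, 3790 higher and 3215 lower (4473 and 2744 after median centring).

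Among the shared changes, AT1G51820 fell by 2.62 ± 0.0889 (SE; limma adjusted p = 1.35e-07) in er-2 and changed by −2.75 (adjusted p = 5.18e-07) in epfl4 epfl6, to a signal below the lower quartile of every array in both. AT1G20150 fell by 3.14 ± 0.42 in er-2 (adjusted p = 0.000752) and changed by −4.50 in epfl4 epfl6 (adjusted p = 6.14e-05). ARL, a gene of organ size control, fell by 1.01 in er-2 (adjusted p = 0.00291) and changed by −1.06 in epfl4 epfl6 (adjusted p = 0.00114). EXLB1, EXPA9, scpl31, GH3.9 and CHX20 rose by at least 1 on the log2 scale in both, and QQS, BGLU28, SBT5.4 and OCT1 fell by at least 1 in both.

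**Figure D4:**
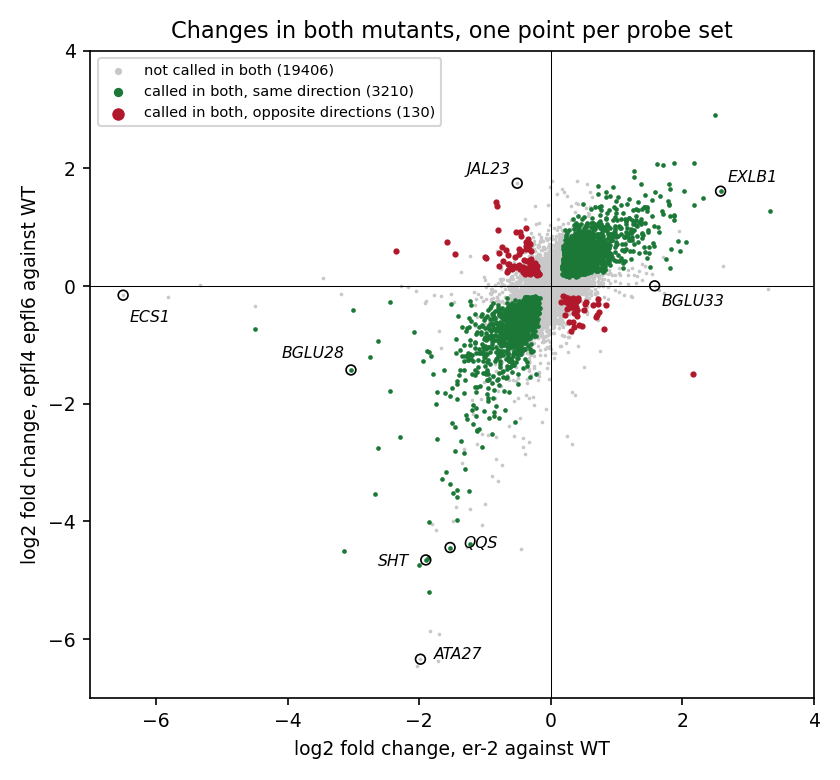
Log2 fold change of each probe set in er-2 (horizontal axis) and in epfl4 epfl6 (vertical axis) against WT, with 8 genes circled. Of the probe sets called in both mutants, 3210 (green) changed in the same direction and 130 (red) in opposite directions; ECS1 lies far to the left and ATA27 far down.

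The direct comparison of er-2 with epfl4 epfl6 asked where loss of the receptor and loss of the ligands differ. It called 4587 probe sets, 2310 higher and 2277 lower in er-2, of which 244 differed at least 2-fold. After median centring it was 1888 higher and 2698 lower. ATA27 was higher in er-2 by 4.36 ± 0.733 (SE; limma adjusted p = 0.00325), with its signal in epfl4 epfl6 below the lower quartile of every array, SHT by 2.76 and QQS by 2.91 ± 0.139 (adjusted p = 2.46e-06). SWEET11 was higher in er-2 by 1.29 (adjusted p = 0.000355), BGLU33 by 1.58 (adjusted p = 2.82e-05), UND by 1.26, nad4 by 1.22 and the chloroplast gene psbA by 1.09. Lower in er-2 was ECS1, with a log2 difference of −6.35 ± 0.100 (adjusted p = 4.68e-10). The differences were −2.26 for JAL23 (adjusted p = 4.42e-05), −1.64 for the pectin methylesterase gene ATPMEPCRB, −1.61 for BGLU28, −1.25 for XTH19, −1.10 for the thionin gene THI2.1 and −0.97 for the senescence-related transcription factor gene WRKY53. Of the 7 lists, 0 passed camera's test in this comparison, 0 at an unadjusted p under 0.05 and 1 by fry, and the smallest camera adjusted p was 0.423, for cell wall loosening. The 3′ minus 5′ difference was 0.461 lower in epfl4 epfl6 than in er-2, and with it as a covariate 66 probe sets were called.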

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

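The tests of the chromosome 1 pattern and of RNAs without a poly(A) tail were chosen after the results were seen; the test of cRNA length or RNA integrity was not. Groups of 3 arrays were not tested for single arrays far from the rest.

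Of the 130 probe sets called in opposite directions in the mutants, 6 with a descriptive symbol differed by at least 2-fold between er-2 and epfl4 epfl6, and they are given because the difference itself passed limma's test with the 3 arrays of each genotype apart. LOV1, a disease resistance-like gene on the upper part of chromosome 1, was higher in er-2 than in epfl4 epfl6 by 1.22 on the log2 scale (adjusted p = 0.000119). The photosystem II gene psbA of the chloroplast genome was higher in er-2 by 1.09 (adjusted p = 0.000118). MCCA, for a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, a gene chosen after its values were seen, was higher in er-2 by 1.05 (adjusted p = 4.73e-05) and also lies on the upper part of chromosome 1. ARPN, for a plantacyanin, rose by 0.72 in epfl4 epfl6 and fell by 0.32 in er-2, a log2 difference of −1.04 (adjusted p = 1.93e-05). TBL26, of a cell wall acetylation family, had a difference of −1.03 (adjusted p = 0.000257), and the cysteine protease gene CP1 had one of −1.02 (adjusted p = 0.00101).

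The position of er-2-specific changes was weighed for 3 explanations. The observation was that 38 of the 51 changes of 2-fold or more lay on chromosome 1, so the tests used changes under 2-fold, and a response to loss of ER signalling with no tie to position was argued against by 65 of 140 of these on chromosome 1, where 10000 random draws gave 36.1 on average and at most 58 (permutation test, p = 1e-04, the smallest these draws can give). A single deletion of the whole region would have lowered all of it, but of its 741 probe sets above a log2 signal of 6 in WT, 2.56% fell at least 2-fold. With 13 of the 32 changes in the region already seen to be higher, this outcome was largely given. Smaller deletions within the region were not tested. A chromosome segment from another line, carried in the er-2 plants, remains a candidate explanation: 44 of the 140, which had not defined the region, lay in it, against 16.4 on average and at most 34 in random draws (permutation test, p = 1e-04), and for epfl4 epfl6-specific changes this was 52 of 411 (permutation test, p = 0.31). These draws take probe sets as independent units and hold no spread between samples. The labels give Col-0 as the background of all samples, ER lies on chromosome 2, and no genotype data were used here, so neither the source of such a segment nor a share of true ER targets within the region was tested.

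The 3′ minus 5′ log2 difference of the control transcripts is a signal outside the main measurement. It was 1.67 in epfl4 epfl6 and 2.45 in WT, without overlap of the arrays, and 11.84 in WT against 11.30 in epfl4 epfl6 was found for the 25S rRNA control.

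Signals of RNAs without a poly(A) tail were weighed against a shift in labelling and against cRNA length or RNA integrity. In epfl4 epfl6 the 25S rRNA control differed from WT by −0.533 ± 0.0879 (SE, n = 3) on the log2 scale, the mean of 16 mitochondrial genes by −0.359 ± 0.0787 and that of 69 chloroplast genes by −0.0981 ± 0.121, so a labelling shift could not be excluded and was not borne out by all of them. In er-2 the chloroplast mean exceeded the mitochondrial mean in its change by 0.281 ± 0.0977, with neither mean over 2 SE from WT. The 25S rRNA control of er-2 differed from WT by 0.00403 ± 0.0627. A labelling shift common to all of them was thus not seen in er-2, but with these spreads it was not excluded there either. The change that the slope on the 3′ minus 5′ difference within genotypes predicted for epfl4 epfl6 correlated across probe sets with the measured change at r = −0.0959, and 168 of 216 reorderings gave a value as high. That explanation and an effect of the genotype on organelle RNA cannot be told apart, because the index differs with the genotype on all arrays.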

How the results depend on the processing

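The fit with the 3′ minus 5′ difference as a covariate was chosen after the results were seen; the other alternatives were fixed in advance. Named calls were rerun with quantile normalization again, median centring, a variance trend with robust estimation, array weights, the replicate block and single arrays left out. No named call was reversed under any of these. The calls of 35 of 35 named genes in er-2 against epfl4 epfl6, 62 of 68 in epfl4 epfl6 against WT and 53 of 62 in er-2 against WT held under all of them. Apart from members taken from the lists, the named genes had been picked for large called changes with the arrays apart, so this was largely given. In er-2 against epfl4 epfl6 no gene was taken from the lists. The differences between the mutants given above for MUTE, WES1, ARR15, RR16 and AUR2 were not rerun. The named calls as a set were not rerun with the covariate, without the dimmest probe sets, with the 2-fold minimum or on 6 arrays. The 32 er-2-specific changes of at least 2-fold on the upper part of chromosome 1 were looked up in the covariate fit of er-2 against WT. Of these 32, which had been picked for large called changes, 24 stayed called in the same direction. Whether the other named calls hold with the covariate was not tested. With a 2-fold minimum the counts were 328 for er-2 against WT, 512 for epfl4 epfl6 against WT, 244 for er-2 against epfl4 epfl6, 368 for the mean of both mutants and 169 for changes shared in direction, by construction of the minimum. With the covariate (3' to 5' index as a covariate) they were 648, 1, 66 and 52, of which 584, 1, 64 and 50 were called without it, and standard errors grew 1.93, 4.15 and 2.58 times in the first 3 comparisons. Other normalizations, filters, variance models and fits on 6 arrays kept every count within 1.5 times. Between both other scalings, median centring moved the split of directions more, to 62.9% higher in epfl4 epfl6 against WT (52.9% as deposited) and to 41.2% higher in er-2 against epfl4 epfl6 (50.4%). With the 2-fold minimum 158 of 512, 161 of 244 and 130 of 368 were higher in epfl4 epfl6 against WT, er-2 against epfl4 epfl6 and the mean of both mutants, and with the covariate 17 of 52 in the last.

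With the replicate number taken as a replicate block, the counts were 4367, 7449, 4248 and 6631, with 2973 shared in direction. The numbers were not taken to pair the arrays, since 3 of 9 arrays correlated best, after removal of genotype means, with those of their own number. Without single arrays, er-2 against WT gave 3257 to 4069 probe sets, epfl4 epfl6 against WT 6264 to 7247, er-2 against epfl4 epfl6 3324 to 4016, the mean of both mutants 5613 to 6925, and the shared changes 2250 to 3105. The correlation of the mutants' changes ranged from 0.6245 without er-2 replicate 3 to 0.676 without er-2 replicate 2.

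Across the 3 comparisons, 3 of 21 list tests passed with the preset correlation. With the estimated correlation it was 0 (2 at an unadjusted p under 0.05). Among the 3 lists that had passed, all in er-2 against WT, the estimate was 0.324 for anther and tapetum and 0.337 for stomatal lineage, far above the preset 0.01. For photosynthesis it was −0.0296, so a higher correlation does not account for that loss, and the cause was not tested. With fry, which does not compare a list with other genes, the number that passed was 10. Without single arrays it was 1 (without WT replicate 2) to 6 (without WT replicate 3), with 5 without WT replicate 1 and 5 without epfl4 epfl6 replicate 2, and the cause was not tested. No alternative gave a value for ER, EPFL4 and EPFL6, which had no named probe set. Signal near the background limits what an array can show, and 30% of probe sets were left out as dimmest in 1 alternative.

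Other splits of the arrays were counted. For er-2 against WT, epfl4 epfl6 against WT and er-2 against epfl4 epfl6 the real counts were 4722, 7707 and 4587 and the highest of the other splits of 6 arrays was 0, with 1 of 10 splits as large, too few for a share under 0.05. Over 100 regroupings of the 9 arrays, the real grouping alone (1 of 100) gave 7005 probe sets for the mean of both mutants, the highest other being 3890. It alone gave 3210 shared changes, the highest other being 1930. A random assignment of arrays to groups was thus argued against for both. The cause is not settled by this, since the 3′ minus 5′ difference of the control transcripts separated the genotypes fully too. For the 3 list calls, 16 of 100 regroupings gave as many, the highest other being 6, so chance was not excluded.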

Other observations

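The test of whether the falls in epfl4 epfl6 came from probe sets near the lower end of the signal was chosen after the result was seen; the test of bud stages was not. Gene families defined by a shared symbol stem were tested with camera as well. They overlapped the lists in part: EXPA4, EXPA8, EXPA15 and EXPA16 were also members of the cell wall loosening list. That list did not pass (camera adjusted p = 0.567 in er-2 and 0.116 in epfl4 epfl6). In epfl4 epfl6, 4 of 10 measured expansin genes of the EXPA family rose and 0 fell (camera adjusted p = 0.0254, adjusted p = 0.487 with an estimated correlation), and in er-2 3 rose and 0 fell (adjusted p = 0.0867), in both cases with the same direction under both other scalings. Expansins loosen cell walls. Of the 69 measured genes of the chloroplast genome, 15 were called higher and 0 lower in er-2 (camera adjusted p = 0.00302, adjusted p = 0.793 with an estimated correlation, and 0.0595 after quantile normalization again). In epfl4 epfl6 5 were higher and 13 lower (adjusted p = 0.26, and 0.00539 after quantile normalization again). In the direct comparison 20 were higher in er-2 and 0 lower (adjusted p = 5.05e-07, adjusted p = 0.707 with an estimated correlation). Of the 16 genes of the mitochondrial genome, 6 fell and 1 rose in epfl4 epfl6 (adjusted p = 0.0254, adjusted p = 0.56 with an estimated correlation). The 25S rRNA control was lower in epfl4 epfl6 too, by a log2 difference of −0.533. No other of the 28 families passed camera's test in any of the 3 comparisons.

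The falls of 4-fold or more in epfl4 epfl6 came in 84 probe sets and were weighed for 2 technical explanations. For falls from near the lower end of the signal, the median WT signal was 7.17, with an SD of 0.467 between the WT arrays. A 4-fold fall to the highest lower quartile of the arrays (3.33) needs a signal of 5.33, and 77 of the 84 were above that in WT. Because the set was chosen for falls of that size, a high WT signal was largely given, so this test could not decide. In epfl4 epfl6, 25 of the 84 had means below that quartile. Different shares of bud stages from sample to sample remain a candidate explanation: within genotypes the set's deviations went together, with a mean pairwise correlation of 0.489, whereas 10000 random sets matched on signal and spread gave 0.0259 on average and at most 0.159. The set's mean was 7.31 ± 0.416 (SD, n = 3) in WT, 6.09 ± 0.661 in er-2 and 4.14 ± 0.0782 in epfl4 epfl6, and the set had been chosen on the same WT arrays. A change in anther development in the mutants, which the genotypes could bring about, stays open and was not tested apart from staging.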
